A study of Homo sapiens with 2 samples.

How the data were processed

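Total RNA of PLC/PRF/5 cells, a human hepatoma line, was taken from 1 sample labelled as given a control lentivirus and 1 labelled as given a hairpin against BAP18. Libraries were made with the Nanopore PCR-cDNA kit SQK-PCS109, per the labels' protocols. Minimap2, a long-read aligner, and the genome build hg38 are named in the submitters' processing notes with no version or role. The counting tool and the annotation release are not given in the sources used here. The authors deposited 1 gene table with 20450 rows. Its counts are whole numbers of reads per gene in each library, per the file headers, and were not normalized. Its CPM columns, also deposited by the authors, equal each count divided by its library's total and scaled to counts per 1e6 reads. The table also holds, for 11620 genes, a value from the tool EBSeq and a log2 fold change made by the authors. Genes marked up or down there all had an EBSeq value of at most 0.00973 and an absolute log2 fold change of at least 1.01. The authors' deposited table gives C17orf49 a log2 fold change of -1.04 and an EBSeq value of 0.978. Columns were matched to samples by name, shCtrl being read as the sample titled shControl, and no per-sample column was left unmapped.

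What follows was computed from the counts. With 1 library per group, edgeR's quasi-likelihood test has no residual degrees of freedom. Each gene was therefore tested with an exact conditional binomial test, two-sided, on its reads in both libraries given library sizes scaled by TMM in edgeR 4.0.16 (R 4.3.3), with factors of 1.02 and 0.98. Genes with at least 20 reads in the libraries together were tested (9337 of 14559 with reads), p-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05 and at least 2-fold. Log2 ratios carry a prior count of 0.5, and intervals are 95% Clopper-Pearson intervals of the read shares. The limit that 0 reads allow (3 reads) was 0.703 CPM in the shBAP18 library and 0.763 CPM in the shControl library. These 2 limits are relative to library totals without TMM scaling, unlike the CPM values given below. For each of 34 gene lists the median log2 ratio of members with at least 20 reads was set against 10000 random lists of the same size, matched on abundance in 10 bins. A list was said to stand apart in the outer 2.5% on either side. No p-value was computed across genes. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, with figures from matplotlib 3.10.9.

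The tests, lists and settings, other than those said to be added, were fixed before the data were examined. So was the rule for the genes named in the text. It takes C17orf49, RNASEK and the measured BPTF/NURF members, then the 10 largest and 10 smallest log2 ratios among called genes with at least 100 reads and a symbol that is not a clone name. For each list it adds up to 4 called members with at least 50 reads, or, for a list apart with fewer than 2 called, its 2 members with the most reads. It gave 70 genes, of which 1 is not reported here, and 49 others were named after their values were seen: list members beyond the rule, genes of the pathways in the closing section, and 5 genes there that are in neither the lists nor the pathways named there. RNASEK-C17orf49 is given besides. Gene positions, GC content and transcript lengths come from GENCODE 29 on the same build, which matched 19974 of the identifiers and gave GC content and length for 96.8% of tested genes. The authors' own annotation release may differ.

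On data simulated from the real means and library sizes with counting noise alone, the test called 28% of genes changed by 1 on the log2 scale in the right direction, 80% at 1.5, 90% at 2 and 100% at 3, and 1 of 9132 unchanged genes. With a simulated coefficient of variation of 0.2 between libraries it called 319 of 9130 unchanged genes (3.49%), against 4.77% of tested genes called in the data. Variation of that size between cultures would by itself give most of such a count. Of 100 random lists of unchanged genes, 6 stood apart. Alternatives were library totals, DESeq2 1.42.0 size factors, minimums of 10 and 100 reads or none, leaving out the 20 most abundant genes, thinning the deeper library, edgeR's exact test with an assumed coefficient of variation of 0.2 or 0.4, other fold minimums, a prior count of 5 and means in place of medians. Corrections for GC content and length, and for abundance as well, by robust regression with terms up to degree 3, were added after seeing the data.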

Results

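The series measured messenger RNA in PLC/PRF/5, a human hepatoma cell line, after transduction with a lentivirus carrying a short hairpin RNA against BAP18 (shBAP18) or with a control lentivirus (shControl). It asked how lowering BAP18, a chromatin-associated protein, alters gene expression in these cells. Each group had 1 library, sequenced as long reads on the Oxford Nanopore platform. The gene table held 4265108 reads for the shBAP18 library, over 13832 genes with reads, and 3932020 reads for the shControl library, over 13552 genes. FTL, the ferritin light chain, took 4.40% and 3.89% of reads. With 1 library per group no difference has a replicate check. The tests below compare these libraries, not the conditions. The 95% intervals cover counting error only and take reads as independent. PCR reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error. Ratios are shBAP18 over shControl.

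The targeted gene is listed as C17orf49 (ENSG00000258315; current symbol BACC1), at chromosome 17, positions 7014495 to 7017525 on the plus strand of hg38. It had 4 reads in the shBAP18 library and 8 in the shControl library, or 0.919 and 2.08 CPM (TMM-scaled read counts relative to library size). The ratio was 0.474 with a 95% interval from 0.0976 to 1.65, so a knockdown was not detectable at this depth (exact binomial test on the reads, two-sided, p = 0.282). The interval covers both a far lower level and a higher one, so the reads do not check the library labels. The gene overlaps RNASEK (positions 7012417 to 7014532), a subunit of the vacuolar proton pump, and the read-through gene RNASEK-C17orf49 (positions 7012635 to 7017520). RNASEK had 4131 and 3727 reads and a ratio of 0.982 (0.939 to 1.03). The read-through gene had 12 and 14 reads and a ratio of 0.767 (0.321 to 1.77). Reads of overlapping genes can be counted at either gene, so these levels are uncertain. Of the 5 measured members of the BPTF/NURF chromatin remodelling complex, to which BAP18 has been assigned, none passed the test. RBBP7, a histone-binding subunit, had a log2 ratio of 0.63 (0.48 to 0.79), above 0 beyond counting error but under 2-fold. BPTF (13 and 7 reads) had 0.68 (-0.71 to 2.28), and SMARCA1, RBBP4 and HMGXB4 had -0.05, -0.03 and -0.05, values that turn positive with library totals as the scale.

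Among 9337 genes with at least 20 reads, 296 were higher and 149 lower in the shBAP18 library, at an adjusted p under 0.05 and at least 2-fold, while 7153 genes (76.6%) lay within 1.5-fold. Among the lower genes with at least 100 reads in the libraries together, the largest fall was that of CA9, a hypoxia-induced carbonic anhydrase, which fell from 108 reads to 5 and was 22.1-fold lower (10.1 to 76.6). FABP1, the liver fatty acid-binding protein, was 4.01-fold lower (3.55 to 4.56; 324 against 1154 reads), and APOA2, an apolipoprotein of high-density lipoprotein, was 3.26-fold lower (3.16 to 3.37; 4915 against 14212 reads). APOC2, the activator of lipoprotein lipase, had a log2 ratio of -2.26 (-2.90 to -1.70) and its read-through APOC4-APOC2 had -2.15. These overlap, so their reads cannot be separated with certainty. The flavin monooxygenase gene FMO5 (-2.10), the complement gene C8G (-1.82), IGFBP1 (-1.73), TMED6 (-1.83) and the cytochrome P450 gene CYP2J2 (-1.70) were the others among the 10 largest falls at that depth.

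Among the higher genes with at least 100 reads, the largest ratios were those of TAGLN, an actin-binding protein of smooth muscle, at 6.08-fold (4.26 to 9.15; 229 against 33 reads), PCSK1N, an inhibitor of prohormone convertase 1, at 5.96-fold (4.36 to 8.49), and C1QBP, a mitochondrial matrix protein, at 4.98-fold (4.18 to 6.01; 806 against 143 reads). TMUB1 (log2 ratio 2.20), the Polycomb protein gene CBX6 (2.18), MARCKSL1 (2.14), CCDC74A (2.03), the lipid kinase gene PIP4K2A (2.02), the transcriptional corepressor gene TLE3 (1.99) and NDRG4 (1.93) followed. In the authors' deposited table, 67 genes are marked up and 57 down. All 67 were also higher here, and 56 of the 57 were also lower. Those marks rest on the same libraries, so the overlap is not a separate check. The counts rest on reads alone. With an assumed coefficient of variation between replicates of 0.2, edgeR's exact test called 20 higher and 12 lower genes, and with 0.4 it called 0 and 0, against 296 and 149 in the test on reads. The share of higher genes among the called genes was 66.5%, and 54.7% (221 higher, 183 lower) after a correction for GC content, transcript length and abundance. With no fold minimum it turned below an even split, at 47.6% (1051 higher, 1157 lower).

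**Figure D1:**
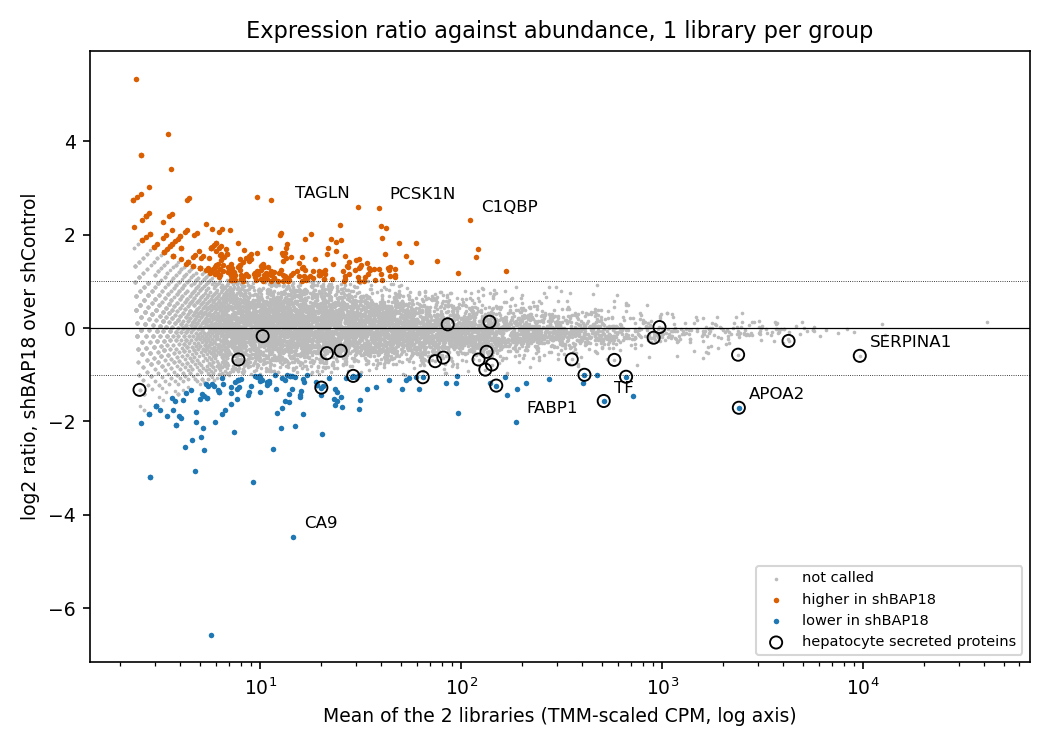
Each point is 1 tested gene, with its mean TMM-scaled CPM in the libraries on a log axis and its log2 ratio (shBAP18 over shControl, prior count 0.5) on the other. Orange and blue points are the 296 higher and 149 lower genes, circles mark the hepatocyte secreted protein list, and dotted lines mark 2-fold; the lowest point is a gene with 0 reads in the shBAP18 library, whose ratio depends on the prior count.

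Genes for proteins that hepatocytes secrete into plasma were lower as a group. Of the 28 measured, 8 fell, none rose, and 25 had a ratio below 0. The list's median log2 ratio was -0.67, below all 10000 random lists of matched abundance, whose central 95% ran from -0.19 to 0.07. These genes took 1.94% of reads in the shBAP18 library and 2.90% in the shControl library. Besides APOA2, the transferrin gene TF fell (-1.56, -1.66 to -1.46; 1127 against 2948 reads), as did ORM1 (-1.27), whose reads can be shared with its near-identical copy ORM2, and the prothrombin gene F2 (-1.23). APOB (-1.05), APOM (-1.04), AHSG (-1.02) and RBP4 (1190 against 2110 reads) lay at the fold minimum, and with library totals as the scale these 4 were no longer called. At an assumed coefficient of variation of 0.2, APOA2 alone of the 8 was still called, and among members of all lists only FABP1, PCK1, CA9 and TAGLN besides. ALB, albumin, had -0.89 (-1.07 to -0.71) and SERPINA1, alpha-1-antitrypsin, the most abundant member, had -0.59 (-0.61 to -0.57), below 0 beyond counting error but under 2-fold. FGG (0.02), APOE (0.08) and AFP (0.14), the fetal liver marker, had intervals that included 0. Of the 17 measured hepatocyte transcription factors none passed the test, and their median of 0.33 lay at the 96.8th percentile of random lists, inside the central 95%. XBP1 had 0.66 (0.53 to 0.79).

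Target genes of PPARA, the nuclear receptor that drives fatty acid oxidation in liver, had a median of -0.25 (0.08th percentile). Of 33 measured, 6 fell and 1 rose. The fallen genes were FABP1, APOA2 (also in the secreted list), ACADS, the short-chain acyl-CoA dehydrogenase (-1.48), the transcription factor gene CREB3L3 (-1.23), ACSL5 (5 against 28 reads) and CIDEC (8 against 33 reads). PDK4, an inhibitor of pyruvate dehydrogenase, rose (1.14, 0.50 to 1.86). CPT1A, the entry enzyme of mitochondrial fatty acid oxidation, had 0.17 (-0.17 to 0.51).

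**Figure D2:**
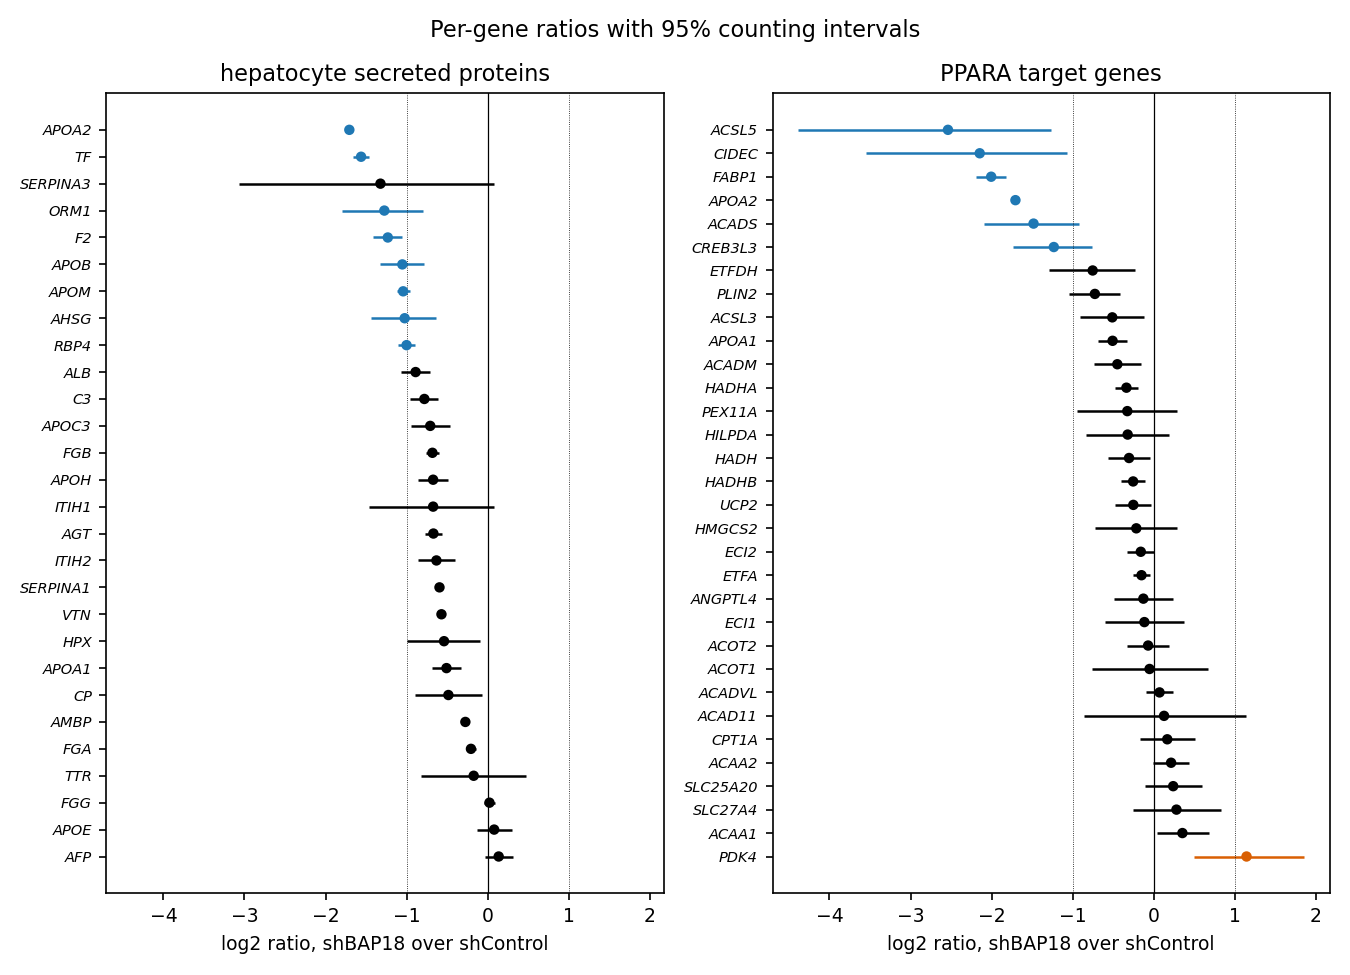
Log2 ratio (shBAP18 over shControl) of each measured hepatocyte secreted protein gene (left) and of 32 of the 33 measured PPARA target genes (right), with bars for 95% counting intervals and 1 library per group. Blue genes were called lower and orange ones higher; 25 of the 28 secreted protein genes lie below 0.

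Other metabolic lists were lower too. Gluconeogenesis and urea cycle genes had a median of -0.57, below all random lists (14 measured, 3 fell). The fallen genes were PCK1, the first committed enzyme of gluconeogenesis, at 4 against 33 reads, pyruvate carboxylase (PC) at -1.57 and GOT1 at -1.08. Of the 14, 12 had a ratio below 0 and 2 above. The list took 0.193% of reads in the shBAP18 library and 0.220% in the shControl library. Its reads as a whole thus fell less than its median gene. Glycolysis genes had -0.33 (0.01th percentile; 20 measured), where the liver pyruvate kinase gene PKLR fell (-1.40), the regulatory kinase gene PFKFB3 rose (1.02), and the abundant ALDOA (-0.54), LDHA (-0.51) and ENO1 (-0.35) stayed under 2-fold. Cholesterol biosynthesis genes had -0.33 (0.02th percentile; 24 measured, 2 fell), with FDPS, farnesyl diphosphate synthase, among the fallen genes (-1.03). SQLE, squalene epoxidase, had 0.66. Drug metabolism genes had -0.43 (0.42th percentile; 8 measured, 1 fell). UGT1A1 fell (-1.21), though genes of its cluster share exons, while CYP1A1 had -0.36 and the very abundant GSTP1 0.09. Lipogenesis genes did not stand apart (0.07; 17 measured), with SCD lower (-1.12), DGAT2 higher (1.14) and FASN at 0.68.

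Of the 34 lists, 9 stood apart as lower and 2 as higher. By chance 1.7 in all would be expected if genes varied independently of each other. Genes regulated together can move together between any cultures, and some lists share genes, so the excess does not exclude chance. Mitochondrially encoded genes were higher (0.27, 99.9th percentile; 13 measured, none called), with MT-ND2 at 0.45 and MT-ND4 at 0.30, while MT-CO1 (-0.05), MT-CO2 (-0.02), MT-CO3 (0.01) and MT-CYB (-0.07) lay near 0; the first 2 of these 4 turn positive with library totals. The p53 target list was lower (-0.30, 0.41th percentile; 20 measured, none called), although BAX, which promotes apoptosis, had 0.72 and TP53I3 had -0.12. The proteasome list was lower by its median (-0.18, 1.80th percentile; 31 measured) with 1 gene, PSMD11, higher (1.59); PSMA7 had 0.09 and PSMB6 -0.20, and its mean of -0.06 did not stand apart. Most markers of other cell types had fewer than 20 reads. These were 10 of the 12 fibroblast and stellate ones, 13 of the 15 on the leukocyte list and 9 of the 10 endothelial ones. The leukocyte list also holds HBB and HBA1, globin genes of red cells and not leukocyte markers. The fibroblast and stellate list had 2 measured genes, COL3A1, which rose (1.25; 103 against 38 reads), and FBLN1 (0.51), and a median of 0.88 (98.2th percentile). The leukocyte list had 2 as well, LYZ (-0.46; 128 against 156 reads) and HBA1 (-1.21; 9 against 19 reads), and a median of -0.83 (1.51th percentile), which turned positive (0.34) with no filter on reads and was no longer apart with at least 100 reads (-0.46). The fibroblast list (0.51) and the drug metabolism list (-0.26) were no longer apart with no filter, nor was the p53 list with at least 100 reads (-0.20). The endothelial list had 1 measured gene, EGFL7, at -0.10 (212 against 201 reads).

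**Figure D3:**
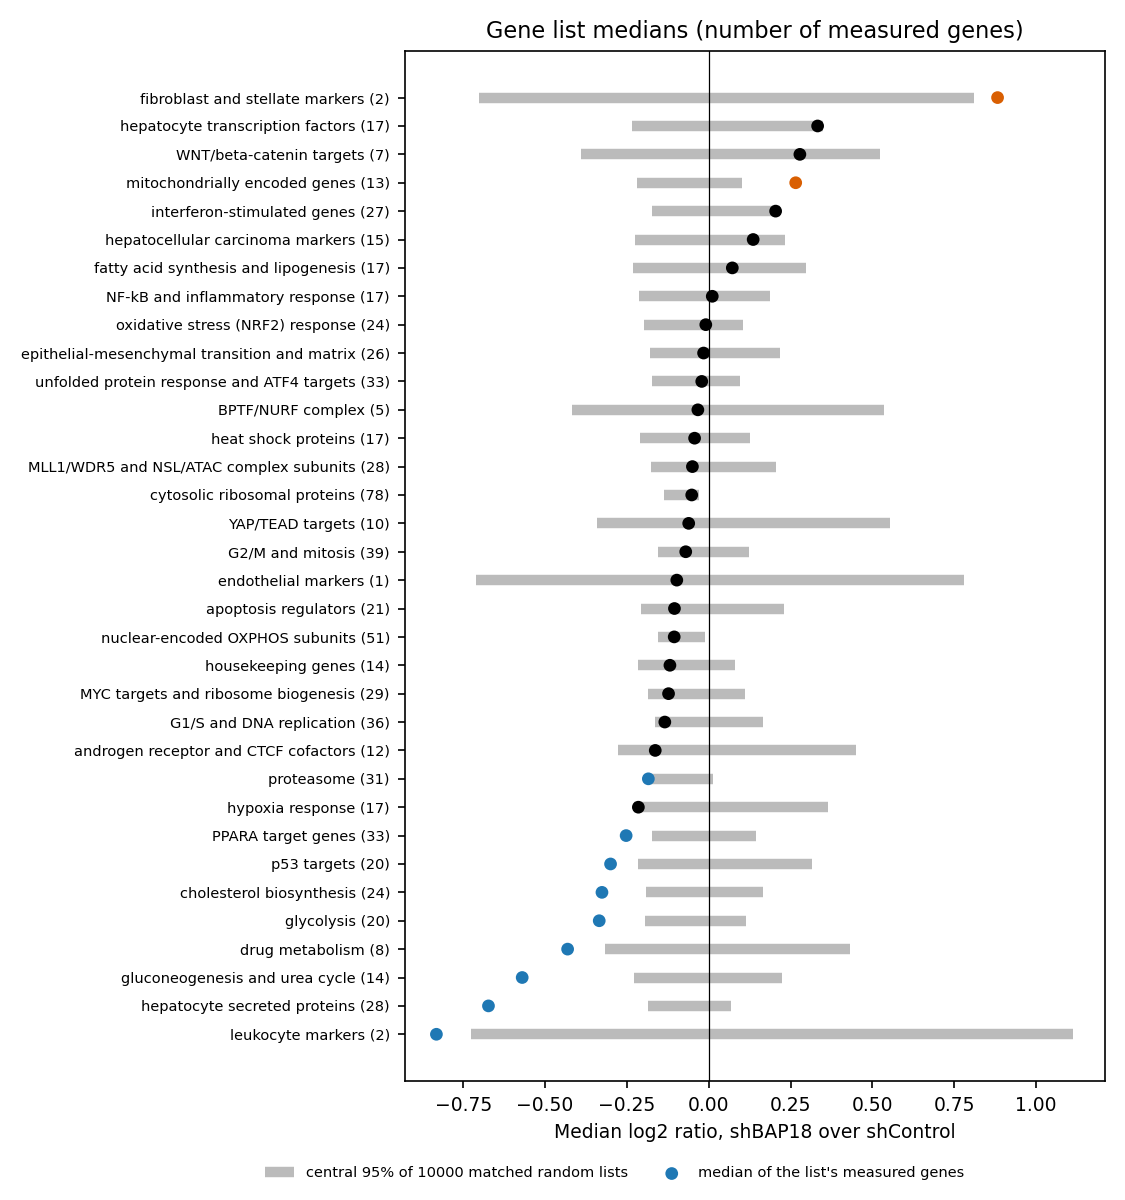
Median log2 ratio (shBAP18 over shControl) of each of the 34 gene lists as a point, with the number of measured genes in brackets, over a grey bar for the central 95% of 10000 random lists of matched abundance. Blue and orange points mark the 9 lower and 2 higher lists; the hepatocyte secreted proteins sit at -0.67.

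The remaining lists did not stand apart in the main test, though 6 of them did under at least 1 alternative. Cell cycle genes had medians of -0.13 (G1/S and DNA replication; 36 measured) and -0.07 (G2/M and mitosis; 39 measured), with 3 genes higher: TYMS, thymidylate synthase (1.22), the DNA polymerase gene POLE (1.14) and CENPA, the centromeric histone (1.45). Hypoxia genes had -0.21 (3.08th percentile; 17 measured), with CA9, ANKRD37 (-1.27) and P4HA1 (-1.03) lower and ADM at 1.00, just under the fold minimum. Interferon-stimulated genes had 0.20 (96.8th percentile; 27 measured), with IRF1 (1.28) and IFI6 (1.14) higher. In the NF-kB and inflammatory list (0.01; 17 measured) 1 chemokine gene, CCL20, fell (-1.30; 477 against 1042 reads) and another, CCL2, rose (2.73, 1.38 to 4.83; 33 against 4 reads). CRELD2 rose (1.27) in the unfolded protein response and ATF4 list (-0.02; 33 measured). In the oxidative stress list (-0.01; 24 measured) AKR1C3 fell (-1.18), subject to reads shared with close paralogs, and SRXN1, sulfiredoxin, rose (33 against 10 reads). TAGLN, EPCAM (1.24) and CYR61 (1.07) rose in the epithelial-mesenchymal transition and matrix list (-0.02; 26 measured). Liver cancer markers had 0.14 (15 measured), with EPCAM and the osteopontin gene SPP1 (1.06) higher and S100P lower (-1.18). Among androgen receptor and CTCF cofactors (-0.16; 12 measured), MED1, a Mediator subunit, rose (41 against 14 reads) and RAD21, a cohesin subunit, fell (-1.18).

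Medians of the other lists were -0.03 for the BPTF/NURF complex, -0.05 for MLL1/WDR5 and NSL/ATAC complex subunits (28 measured), -0.10 for apoptosis regulators (21, with the caspase inhibitor gene XIAP lower at 11 against 25 reads, no longer called with library totals), -0.04 for heat shock proteins (17), -0.05 for cytosolic ribosomal proteins (78), -0.12 for MYC targets and ribosome biogenesis (29), -0.11 for nuclear-encoded OXPHOS subunits (51), 0.28 for WNT/beta-catenin targets (7), -0.06 for YAP/TEAD targets (10) and -0.12 for housekeeping genes (14). Library totals in place of TMM raise the median of all tested genes by 0.06, so no direction is read from list medians closer to 0 than that. Adjusted over the list alone, the counts of called genes were the same as over all genes, with these exceptions. Lipogenesis had 3 in place of 2, and the unfolded protein response and ATF4 list 3 in place of 1. The mitochondrially encoded genes had 1 in place of 0. The leukocyte list also had 1 in place of 0, the globin gene HBA1. Other calls ended under alternatives too, among them FDPS and P4HA1 with library totals and P4HA1, PFKFB3 and SPP1 with the deeper library thinned. POLE and PFKFB3 were among those that ended after correction for GC content and length. Of the 119 genes picked for naming, 5 calls ended with thinning. Another 5 each ended after correction for GC content and length and with abundance corrected as well, with overlap possible.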

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

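The GC content, length and abundance corrections, the pathway tests and the exclusion of list members were chosen after the results were seen. The BAP18 ratio kept its direction and stayed within counting error under every scaling tried, with log2 values from -1.33 (deeper library thinned) to -1.02 (library totals); its 12 reads are the limit. The counts of higher and lower genes stayed within 1.5 times with library totals (329 and 118), DESeq2 size factors (289 and 155), a minimum of 10 reads or none, thinning, the 20 most abundant genes left out, and both corrections. They were 110 and 72 with at least 100 reads, where fewer genes are tested, 610 and 369 at 1.5-fold, and 1051 and 1157 with no fold minimum. With edgeR's exact test they were 20 and 12 at an assumed coefficient of variation of 0.2, and 0 and 0 at 0.4. Most genes with at least 100 reads varied less between these libraries than a coefficient of variation of 0.2 would give. The real spread of each single gene between cultures is unknown, so it is the main limit on every call. The lists of hepatocyte secreted proteins, PPARA targets, gluconeogenesis and urea cycle, glycolysis, cholesterol biosynthesis and mitochondrially encoded genes stood apart on the same side in every alternative run on lists. The secreted list's values ran from -0.72 to -0.60. The p53 list no longer stood apart with at least 100 reads (-0.20), nor did the leukocyte markers (-0.46), where fewer members are measured. With no filter on reads, drug metabolism (-0.26), the proteasome (-0.18) and the fibroblast and stellate markers (0.51) no longer stood apart. The leukocyte markers turned positive (0.34). The setting adds members with few reads to each of these lists except the proteasome. There all 31 members were already measured and the median did not change. Only the random lists it was set against did, which moved its percentile from 1.80 to 2.65. The proteasome list also failed to stand apart as a mean (-0.056) and after correction for GC content and length (-0.11) or abundance as well (-0.040). Of the 23 lists not apart in the main test, 6 stood apart in at least 1 alternative: interferon-stimulated genes with at least 10 reads (0.25), with thinning (0.25) and after correction for GC content and length (0.20), MYC targets after the same correction (-0.20), NF-kB genes with at least 100 reads (-0.26), hypoxia genes as a mean (-0.45), hepatocyte transcription factors with a prior count of 5 (0.31) and liver cancer markers after correction for abundance as well (0.27). Of 119 genes (the 70 the rule gave and 49 others), 10 called ones fell short of a call with library totals and none with DESeq2 size factors, 63 did at an assumed coefficient of variation of 0.2, and none of these genes' called values changed sign.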

Other observations

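The tests on transcription factors, on the read totals of overlapping genes and on exchanged labels were chosen only after the results they address were seen, as were the pathways, the corrected values and the genes named here beyond the fixed rule. The deposited pathway annotation gave 266 KEGG pathways with at least 10 measured genes. Of these, 40 stood apart as lower and 49 as higher. By chance 6.65 on each side would be expected if pathways shared no genes and genes varied independently of each other. After correction for GC content, length and abundance, 34 of the 40 and 38 of the 49 still stood apart. Complement and coagulation cascades had a median log2 ratio of -0.47 (33 measured, 7 fell), and without the genes of the preset lists the remaining 26 had -0.31, at the 0.07th percentile of random lists. Besides F2 and C8G, the fallen genes were SERPINF2, the antiplasmin gene (-1.82), F12 (-1.37), CPB2 (-1.31), C8A (-1.19; 15 against 31 reads) and F7 (-1.03). PPAR signaling had -0.45 (37 measured, 7 fell), with ACSL4 (-1.52) and ACOX2 (-1.10) beyond the preset lists. Fatty acid degradation had -0.34, tryptophan metabolism -0.37, with GCDH lower (-1.05), arginine biosynthesis -0.52, fat digestion and absorption -0.48 and the citrate cycle -0.31. F7, C8A and GCDH were no longer called with library totals.

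Among the higher pathways, Wnt signaling had a median of 0.32 (62 measured; 5 higher, 2 lower), with the receptor genes FZD4 (2.28; 24 against 4 reads) and FZD5 (1.57) and the ligand gene WNT3 (37 against 14 reads) higher. MAPK signaling had 0.28 (122 measured, 13 higher, none lower), including FLNA (1.27; 226 against 83 reads) and MAP3K12 (2.12). ErbB signaling had 0.32 with no called gene, ECM-receptor interaction 0.34 with SDC1 (1.25) and SPP1 higher, and heparan sulfate biosynthesis 0.48 with NDST1 higher (1.32). After correction these medians were 0.25, 0.19, 0.29, 0.23 and 0.42. Without preset list members ECM-receptor interaction was no longer apart (0.34, 95.7th percentile). WNT3 was no longer called after correction for GC content, length and abundance, nor FLNA after correction for GC content and length. Outside the preset lists and the pathways named here, CES1, a liver carboxylesterase, had 0 against 44 reads. MUC13 (7 against 65 reads) and LGALS4 (14 against 77 reads), genes of intestinal epithelium, and the abundant TMED9 (1679 against 4052 reads) and HLA-DMB (397 against 949 reads) were lower too.

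Of the lists that stood apart, the hepatocyte secreted protein genes, which were lower, had the most reads (82893 and 114031). After correction for GC content, length and abundance the list's median was -0.60, at percentile 0 of random lists, which argues against those trends as its whole cause. A lower yield of secreted-protein mRNAs in general is argued against by 281 other genes annotated as extracellular, whose median was 0.068 (bootstrap interval -0.01 to 0.14). Left out of that set were the secreted, PPARA, drug metabolism, gluconeogenesis and urea cycle and liver cancer lists. The complement and PPAR pathways were left out too. All of these but the liver cancer list were lower, so the value speaks only for extracellular genes outside them. A lower share of hepatoma cells was tested with 2 values. The SD of the members' ratios, 0.458, at the 91.6th percentile of random lists, did not exclude a common fall. Random lists have their own spread between genes, so that percentile cannot show whether members fell alike. The SD exceeded 0.153, the median counting SD of genes with at least 100 reads. APOA2 had -1.71 (-1.75 to -1.66), SERPINA1 -0.59 (-0.61 to -0.57) and FGG 0.02 (-0.04 to 0.09). These values argue against a lower share, which would lower all members alike, as the whole cause. The later test was chosen after the median of the hepatocyte transcription factors had been seen. That median, 0.33 (-0.26 to 0.53) against -0.67 (-0.94 to -0.55), argues against a common fall. It does so only if hepatoma cells alone supplied the mRNA of these factors, which was not tested. Corrected, the values were 0.20 (-0.44 to 0.33) against -0.60 (-0.87 to -0.51). These intervals resample genes, not cultures, so a lower share was not excluded as part of the fall. Fibroblast and stellate markers (2 measured) were higher, at 0.88, while the leukocyte list (2 measured) was lower, at -0.83. So few genes cannot decide the question. A change in hepatocyte gene expression after BAP18 knockdown remains a hypothesis. Culture density, clonal drift or any other difference between these 2 cultures may also account for the fall, and none of these was tested. Replicate cultures with a second hairpin, and a rescue with hairpin-resistant BAP18, would test it.

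More genes were higher than lower in the shBAP18 library (66.5% of called genes), but only with a fold minimum: with none, 1051 were higher and 1157 lower (47.6% higher). Median ratios rose with GC content, from -0.09 in genes of 31.8% to 39.0% GC to 0.17 in those of 61.6% to 74.5% GC, and fell with abundance. After correction for GC content and length the share was 58.1% (95% interval 53.1 to 62.9), and with abundance corrected as well 54.7% (49.7 to 59.6). These intervals take called genes as independent, which genes of the same libraries are not, and leave out the choice of scale. Library totals alone moved the uncorrected share to 73.6%. A technical difference in GC content, length or abundance between the libraries is thus a candidate explanation for the excess at 2-fold; a biological effect on genes of that kind stays open and was not tested.

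The targeted gene had too few reads to show a knockdown. Reads counted at the overlapping RNASEK genes cannot be told apart from it, since the 3 genes together had a ratio of 0.980 (0.938 to 1.02) and RNASEK holds nearly all of those reads. Exchanged labels cannot be told apart either, since the ratio of C17orf49 itself, 0.474 (0.0976 to 1.65), includes 1. A real knockdown stays open, since the reads at this depth resolve neither its presence nor its absence.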
